A study of Mus musculus with 6 samples.

How the data were processed

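RNA was measured in soleus muscle of 6 mice on a low-density DNA array, 1 array per mouse. Per the labels' protocols, total RNA came from cryosections of the muscle belly and was isolated with a column kit. A 4 microgram amount was reverse transcribed with primers for the array's genes, and [alpha-32P]dATP was incorporated, so that each spot was read as radioactivity. The scanner, the background treatment and the normalization are not given in the sources used here.

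The table the authors deposited holds 223 probes and 6 columns of linear signal, 1 per mouse, and none of its 1338 values is at or below 0. Without probes 1M and 1O, the other 221 probes summed to between 0.999 and 1.00 on every array. The deposited signal is therefore treated here as each probe's part of the array's total over those 221 probes, and is given as parts per mille. This scale was found from the values, and no label states it. A consequence is that a bright probe that rises on an array lowers every other probe there. All values but 1 are given to 4 decimals (tolerance 1e-06 after scaling to that step), so the step between values was 0.1 per mille. The lowest signals lay close together on each array, with a 10th percentile of 0.5 to 0.7 per mille, which resembles background that was not subtracted. That percentile is called the floor of the array here. A probe was called clear of the floor in a mouse when its signal was at least 2 times the floor of that array; this definition was chosen after the values were seen. Being clear of the floor is a statement on the probe's own spot. Levels of different probes were not ranked against each other, because spots differ in the efficiency of their primers and hybridization. The deposited values give no spot replicates and no depth, and the number of arrays limits the precision.

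Gene names came from the platform's annotation, which named 1 gene for each of 205 probes, several genes for 0 and none for 18. Of these, 204 were found by gene number in a current table of mouse genes (GRCm38.p6), and 1 kept the platform's name. The names cover 203 genes, since Igf1 and Fn1 have 2 probes each. Gene lists used the probe with the higher mean signal of such a gene. Cross-hybridization between close relatives, such as the myosin heavy chains Myh1, Myh2 and Myh4, the aldolases Aldoa and Aldoc, or Ang and Ang2, could not be examined with these files.

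The labels put all 6 samples in 1 group and name no untreated or unloaded muscle, so no effect of reloading was tested. The samples are named by the number in their titles, 175, 176, 177, 178, 202 and 203. The series text calls them biological replicas. Signals were used on the log2 scale as deposited, with no pseudocount. For each probe the standard deviation (SD) over the 6 mice was computed. With 1 array per mouse, differences between mice cannot be told apart from differences between labellings and arrays. The design, 27 gene lists, the alternatives and the rule for named genes were fixed before the data were examined. The array held 3 or more members of 14 lists, 1 or 2 members of 6 and none of 7. For each of the 14, the median SD of its members and their mean pairwise Pearson correlation over mice were set against 10000 random lists of the same size matched on the 4 quartile bins of mean signal. A list stood apart at or above the 97.5th percentile, or for the SD also at or below the 2.5th; these percentiles describe these samples, and genes are not independent replicates. Scores of the 91 pairs of lists were compared over mice with exact permutation tests over all 720 pairings, two-sided, with Benjamini-Hochberg adjustment. The title numbers fall into a run from 175 to 178 and a run of 202 and 203. The labels do not say what the runs are, and a difference between them was tested as a possible batch, with limma (lmFit and eBayes) and Benjamini-Hochberg adjustment over 223 probes.

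The rule named the 6 probes with the largest and the 6 with the smallest SD after leaving out the dimmest 25% of probes, the first 2 measured members of each of the 14 lists, and Tnc, Myh7, Myod1, Myog, Cdkn1a and Igf1, in all 40 probes. Genes named beyond it were chosen after their values were seen. The alternatives were centring each array on its median, quantile normalization, leaving out the dimmest 25% of probes, a pseudocount of 0.6 per mille, the median absolute deviation, Spearman's correlation, unmatched random lists, a median list score and leaving out each mouse. Dividing each array by its floor, subtracting 50% of its floor, keeping only probes clear of the floor, leaving out samples 202 and 203, and a term for the number run were added after the data were seen.

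The tests were checked on 20 simulated data sets of 223 independent probes, with the observed means and the spread of each probe within the number runs. In the comparison of samples 202 and 203 with the other 4, limma called 46.0% of probes changed 1.5-fold, 80.2% of those changed 2-fold, 96.8% of those changed 3-fold and 1.2% of unchanged probes. For this comparison each data set held 20 probes raised at each fold and 163 unchanged probes. With fewer changed probes the shares called after adjustment may be lower. In the list covariation step, a shared factor was planted in the fatty acid metabolism list of 12 genes only. It reached the 97.5th percentile in 100% of the data sets, and lists of other sizes were not planted. Of the other lists 2.3% reached that percentile, a share that holds for independent probes, which real probes are not. R 4.3.3, limma 3.58.1, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.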

Results

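Gene expression was measured in the soleus, a postural hindlimb muscle, of 6 mice of the 129/SV strain labelled WT. The hindlimbs had been unloaded by suspension for 7 days, and the muscle was then reloaded for 1 day. All 6 samples carry this condition, so the measurements give the signal of each probe in reloaded muscle and its spread between mice. Signals are parts per mille of the total of 221 probes on each array. The floor of the arrays lay between 0.5 and 0.7 per mille, and between 68 and 88 of the 223 probes were clear of it on a given array. In all 6 mice 57 probes were clear of the floor, 45 were clear in 1 to 5 mice and 121 in no mouse. A probe in the last class had a signal too close to the floor to be read as expressed or as not expressed.

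All measured genes of the slow and fast contractile, structural, oxidative phosphorylation and citrate cycle lists were clear of the floor in every mouse. Myh7, the slow myosin heavy chain, gave 69.1 ± 15.4 per mille (SD, n = 6), which was 115 ± 35.1 times the floor. All 3 measured genes of the fast contractile list were clear of the floor: Myh2 gave 23.0 ± 7.24, Myh1 40.8 ± 8.75 and Myh4 13.2 ± 3.29 per mille (SD, n = 6). Desmin (Des), the muscle intermediate filament, gave 36.2 ± 10.3 and titin (Ttn), the molecular spring of the sarcomere, 20.6 ± 3.20 per mille (SD, n = 6). All 3 measured cytochrome c oxidase subunits of the oxidative phosphorylation list, the terminal complex of the respiratory chain, were clear of the floor. Cox4i1 gave 17.4 ± 1.22, Cox5b 22.2 ± 1.83 and Cox6a2 51.0 ± 10.5 per mille (SD, n = 6). Both measured members of the citrate cycle list were clear of the floor, Mdh2 at 4.08 ± 0.147 and Pdha1 at 5.22 ± 0.387 per mille (SD, n = 6). Myoglobin (Mb), the muscle oxygen store, gave 58.7 ± 7.62 per mille, and carbonic anhydrase 3 (Car3), the only member measured of the calcium and ion handling list, 15.7 ± 2.31 per mille (SD, n = 6).

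Fuel use genes were divided. In the glucose metabolism list 5 of 8 genes were clear of the floor in all mice, among them Slc2a4, the insulin-responsive glucose transporter, at 4.13 ± 0.731 per mille and Aldoa, a glycolytic aldolase, at 144 ± 28.8 per mille (SD, n = 6). The others of the 5 were Gapdh, Pgk1 and Ldhb, whereas Ldha and Slc2a1 were clear in some mice and Hk1 in none. In the fatty acid metabolism list 7 of 12 genes were clear in all mice. Lpl, the lipase that releases fatty acids from lipoproteins, gave 3.0 ± 0.460 per mille, Cd36, a fatty acid transporter, 4.52 ± 1.23 and Fabp4, a fatty acid binding protein abundant in fat cells and capillaries, 5.55 ± 1.23 per mille (SD, n = 6). Cpt1b, which admits fatty acids to mitochondria, gave 1.38 ± 0.117 per mille (SD, n = 6) and was clear in 4 of 6 mice. Lipe and the receptors Ppara and Pparg were clear in no mouse.

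**Figure D1:**
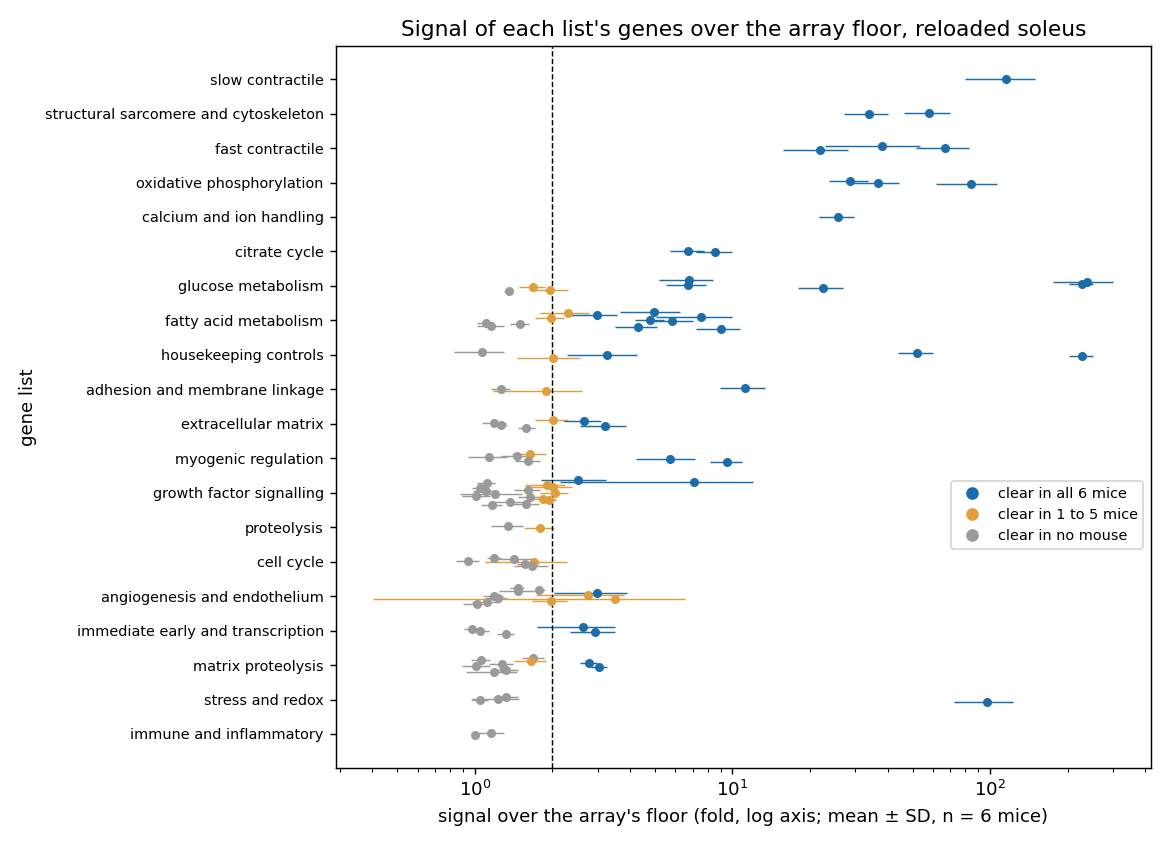
Each point is a gene of a fixed list, placed by its signal over the floor of the array on a log axis (mean ± SD, n = 6 mice), and the dashed line marks 2 times the floor. The 3 fast myosin genes and the 3 cytochrome c oxidase genes lie far to the right of the line, whereas 5 of 6 cell cycle genes and 7 of 10 matrix protease and inhibitor genes were clear of the floor in no mouse.

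In the myogenic regulation list 2 of 6 genes were clear in all mice: Myf6, a regulator of mature fibres, gave 3.53 ± 1.00 and Mef2c, its transcriptional partner, 5.90 ± 1.34 per mille (SD, n = 6). Myod1, a determination factor of activated satellite cells, gave 1.02 ± 0.214 per mille and was clear in 1 mouse, and Myog, a differentiation factor, gave 0.900 ± 0.141 per mille and was clear in none (SD, n = 6). None of the 6 cell cycle genes was clear in all mice. Ccnd1 gave 0.733 ± 0.0816 and Cdkn1a, a cyclin-dependent kinase inhibitor, 0.883 ± 0.204 per mille (SD, n = 6). In the immediate early and transcription list Jun and Srf were clear in all mice, at 1.60 ± 0.506 and 1.78 ± 0.293 per mille, and Junb was clear in none, at 0.60 ± 0.0894 per mille (SD, n = 6).

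In the extracellular matrix list 2 of 6 genes, fibronectin (Fn1) and the laminin chain Lamc1, were clear in all mice. Fn1 gave 1.63 ± 0.294 per mille (SD, n = 6) on its brighter probe, whereas its other probe, annotated to the same sequence, gave 0.60 ± 0.110 per mille and was clear in no mouse. Tnc, which encodes tenascin-C, a matrix protein of mechanically stressed tissue, gave 1.23 ± 0.197 per mille (SD, n = 6), 2.01 ± 0.293 times the floor, and was clear in 3 of 6 mice. In the matrix proteolysis list the inhibitors Timp2 and Timp3 were clear in all mice, and 7 of 10 members in none, including the gelatinases Mmp2 at 1.05 ± 0.226 and Mmp9 at 0.650 ± 0.0837 per mille (SD, n = 6). Of the adhesion genes, Itgb1, the common integrin beta chain, gave 6.95 ± 1.81 per mille and was clear in all mice, and Itgav gave 0.783 ± 0.147 per mille and was clear in none (SD, n = 6).

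Of 17 growth factor genes, only Igf1 and Igf2, ligands of the insulin-like growth factor system, were clear in all mice. The brighter Igf1 probe gave 1.53 ± 0.393 per mille, and the other Igf1 probe gave 1.03 ± 0.186 per mille and was clear in 2 mice (SD, n = 6). Igf2 gave 4.10 ± 2.49 per mille (SD, n = 6). In the angiogenesis and endothelium list 1 of 11 genes, the endothelial adhesion molecule Pecam1, was clear in all mice, and the growth factor Vegfa, at 0.900 ± 0.0894, and its receptor Kdr, at 1.10 ± 0.167 per mille (SD, n = 6), were clear in none. In the stress and redox list Mb alone of 4 genes was clear, and Hmox1 gave 0.817 ± 0.133 and Nos2 0.75 ± 0.138 per mille (SD, n = 6). The inflammatory cytokines Il6 and Il1b were clear in no mouse, nor was Capn3 of the proteolysis list, whose other member, Cast, was clear in some. Of the 5 control genes of the housekeeping list, Rps29 gave 31.6 ± 2.42 per mille, and Hprt 0.667 ± 0.216 per mille and was clear in no mouse (SD, n = 6). No probe was measured for the lists of developmental and denervation genes, kinases and phosphatases, apoptosis, high-energy phosphate and lactate, blood, fat cells, or nerve and Schwann cells, so contributions of those cell types were not examined here.

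The spread between mice, which with 1 array per mouse includes that between arrays, ranged widely over the probes. The SD of log2 signal over the 6 mice had a median of 0.27 over the 223 probes, which was 0.15 with a pseudocount and 0.17 with quantile normalization. The 6 narrowest probes after leaving out the dimmest 25% were Mdh2 (SD 0.05 on the log2 scale), Top3a (0.10), Cox4i1 (0.10), Angpt1 (0.11), Acadm (0.11) and Cox8a (0.11). Top3a and Angpt1 were clear of the floor in no mouse. Some of these narrow spreads depended on the scaling. With arrays centred on their median the SD was 0.17 for Mdh2, 0.15 for Top3a, 0.19 for Cox4i1, 0.13 for Angpt1, 0.17 for Acadm and 0.13 for Cox8a, and with quantile normalization it was 0.14 for Mdh2, 0.21 for Top3a, 0.16 for Cox4i1, 0.09 for Angpt1, 0.17 for Acadm and 0.28 for Cox8a, against a median of 0.17 over all probes in that setting. The 6 widest were the unnamed probe 10C (SD 1.41), Angpt2, a vascular ligand (1.12), Il6st, the shared receptor subunit of interleukin 6 (0.95), Igf2 (0.84), angiogenin (Ang, 0.75) and the binding protein Igfbp6 (0.64). In all, 12 probes had an SD above 0.5, among them Myh2 at 0.52, which fell to 0.28 without sample 175. This count was 37 with 50% of its floor subtracted from each array, 4 with a term for the number run and 6 with only probes clear of the floor. All 6 of the widest probes were among the 10 that were higher in samples 202 and 203. No list stood apart from matched random lists in its median SD: the lowest was oxidative phosphorylation at 0.12 (percentile 3.98), and the highest percentiles were those of adhesion and membrane linkage (93.5), housekeeping controls (93.3) and fast contractile genes (91.7). With a term for the number run 3 lists stood apart, the fast contractile list at percentile 97.8, adhesion at 98.9 and growth factors at 98.4.

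Members of both matrix lists varied together over the 6 arrays, and with 1 array per mouse this cannot be assigned to the mice. The 10 matrix protease and inhibitor genes had a mean pairwise correlation of 0.77 over the 6 mice, at percentile 99.96 of matched random lists, whose median was 0.28. Of these 10 genes, 7 were clear of the floor in no mouse, as were 3 of the 6 extracellular matrix genes, and the step between values is 0.1 per mille. The 6 extracellular matrix genes had a mean correlation of 0.69, at percentile 99.4, against 0.12 in random lists. By chance 0.35 of the 14 lists would reach the limit set for a list to stand apart. The growth factor list lay at percentile 96.6 and the myogenic list at 96.1, below that limit. The growth factor list passed it with quantile normalization (98.1), with Spearman's correlation (99.1) and without sample 177 (98.0), and the myogenic list without the dimmest 25% of probes (99.9) and without sample 175 (98.0), but the myogenic list fell to 67.8 with arrays centred on their median and 35.8 with quantile normalization. The 4 stress and redox genes had a mean correlation of -0.17, at percentile 1.20. Both matrix lists fell below the limit without sample 202, to percentiles 70.4 and 83.8, where the growth factor and housekeeping lists reached it instead (97.6 and 97.9), and with a term for the run of sample numbers, to 96.9 and 90. The extracellular matrix list also fell below the limit with quantile normalization (95.2) and with arrays divided by their floor (77.1). Of the 91 pairs of list scores, 0 passed an adjusted p of 0.05 in exact permutation tests (Benjamini-Hochberg, smallest adjusted p = 0.0903, n = 6), while 19 had an unadjusted p under 0.05, and with permutation within number runs these counts were 0 and 13. Within runs only 48 pairings exist, so that no p there can lie under 0.0208 (exact permutation) and a count of 0 after adjustment over 91 pairs says little. Single correlations of list scores are not given, because samples 202 and 203 stood apart from the others and neither part holds 6 samples.

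Samples 202 and 203 differed from samples 175 to 178 in 14 probes, a comparison that answers whether the runs of title numbers differ as batches would and is not one of the study. Over all probes, log2 signals of array pairs correlated at a median r of 0.975 (15 pairs, across genes, which are not independent). Pairs within a number run had r from 0.979 to 0.993, and pairs across runs from 0.956 to 0.975. In limma, 14 probes passed an adjusted p of 0.05, 10 higher and 4 lower in samples 202 and 203, against a median shift of all probes of -0.18 on the log2 scale. Samples 202 and 203 also had more probes clear of the floor, 83 and 88 against 68 to 75, and a lower signal of the unnamed probe 1M, 968 and 1214 per mille against 1295 to 1645. The floor was 0.5 per mille in sample 202, 0.6 in samples 175, 176 and 203, and 0.7 in samples 177 and 178. Part of the difference in probes clear of it may come from these steps. At the same floor, sample 203 had 88 such probes against 75 and 73 in samples 175 and 176. Of the 10 higher probes, 3 were clear of the floor in all of samples 175 to 178: Igf2 was 2.93-fold, Il6st 3.0-fold and Igfbp6 2.24-fold higher, with limma adjusted p-values of 0.000101, 0.00141 and 0.00108. With only probes clear of the floor in all mice, 2 of these 3 passed. With arrays centred on their median, Il6st did not (limma adjusted p = 0.0591). The rest of the 10 higher probes lay near the floor in some or all of samples 175 to 178, so no fold is given for them. Angpt2 gave 3.7 and 4.5 per mille in samples 202 and 203 against 0.7 to 1.2 in the others (limma adjusted p = 7.17e-06), probe 10C 8.1 and 8.7 against 1.0 to 2.7 (limma adjusted p = 9.65e-06) and Ang 2.0 and 2.6 against 0.8 to 1.3 (limma adjusted p = 0.000912). The other 4 higher probes, named after their values were seen, were Csf2rb2, a cytokine receptor chain, the meiotic cyclin Ccna1, the angiogenin relative Ang2 and the cyclin-dependent kinase Cdk4. In each of the 10, both samples lay above all 4 others. Lower in samples 202 and 203 were the triglyceride synthesis gene Dgat1, at 1.1 per mille in both against 1.6 to 2.4 in the others, and Hprt, the sperm membrane gene Adam2 and probe 7O, which were clear of the floor in no mouse, so that their differences lie within signals near the floor. With each array divided by its floor, 19 probes were higher and 3 lower, among them 8 of the 10 and 1 of the 4. Without sample 175 or without sample 176, 8 and 5 of the 10 higher probes passed and 0 of the 4 lower. After quantile normalization 7 of the 10 higher and 2 of the 4 lower probes passed, with Il6st, Ccna1, Ang, Dgat1 and Hprt past 0.05 no longer, and without sample 202 or without sample 203, which leaves 1 sample in that run, 0 of the 10 did.

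**Figure D2:**
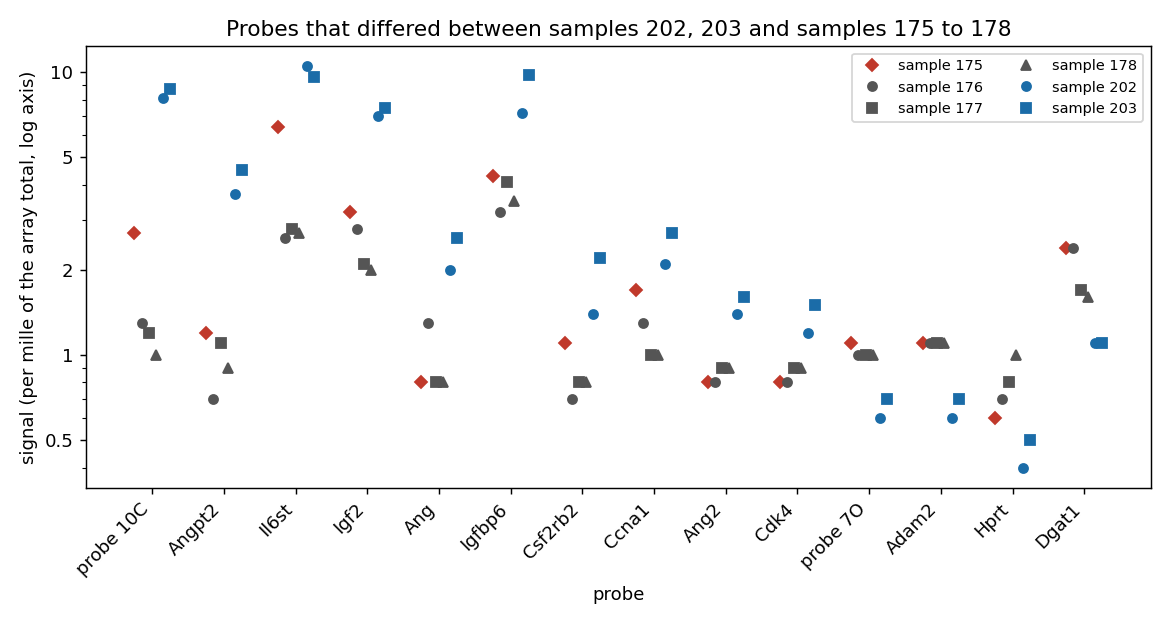
Signal in parts per mille (log axis) of each of the 14 probes that differed between the runs of sample numbers, with 1 point per mouse. In the 10 probes at the left, samples 202 and 203 (blue) lie above samples 175 to 178, and sample 175 (red) lies highest of those 4 in 7 of the 10.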

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

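In this part, the tests of position and of array-wide level were set before their results were seen, and the tests of the array floor and the number runs were chosen afterwards. Leaving out each mouse was planned, but sample 202 was taken up as an explanation only after the results were seen. A value was singled out when the gap between the highest or lowest mouse and its nearest neighbour exceeded the critical value of Dixon's test for 6 values. Of 60 sets of 6 values tested, 9 were singled out, and chance alone gives about 3 for separate sets. The sets are not separate, since they share the same 6 arrays and include list scores beside members of those lists. In sample 202, 66.8% of all probes were at or tied for their lowest value. The 9 are therefore not a count of separate outliers. Sample 203 was highest in Jun (gap 0.628 of the range) and in both Igf1 probes (0.762 for the dimmer and 0.657 for the brighter). Sample 202 was lowest in Cdkn1a (0.745) and Fn1 (0.686) and highest in Cpt1b (0.643). Sample 202 was also lowest in the scores of the cell cycle list (0.711), the matrix proteolysis list (0.711) and the adhesion list (0.657).

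The matrix protease and inhibitor genes moved together between mice, each measured on 1 array. If the number in a probe's name is a position, the list lay at percentile 99.92 among random lists with the same numbers. Those lists had a median correlation of 0.58 against 0.77 for the list. This cannot decide on position, which stays open. Many members share a number that few other probes carry, so the random lists consisted in large part of the same probes. Those probes include the further matrix proteases Mmp10 and Mmp11. The level of the arrays, taken as their median, is argued against, as the list stayed at percentile 99.95 with arrays centred on it. Between samples 177 and 202 the floor fell from 0.7 to 0.5 per mille and the median from 1 to 0.8 per mille. The floor thus fell by more in proportion, so centring need not take out the level of probes near the floor. The list lay at 98.4 with arrays divided by their floor and at 99.95 with 50% of the floor subtracted. These values do not decide on the floor, since 7 of the 10 members were clear of it in no mouse. The floor and these signals also move in steps of 0.1 per mille, and the subtraction left part of the floor in. A difference between the number runs cannot be told apart from the pattern, because the percentile of 96.87 with a term for the run lay just under the limit, with only 6 samples. The pattern may rest on sample 202, without which the list lay at percentile 70.36: all 10 members were at or tied for their lowest value there, as were 66.8% of all probes, and no biological explanation was tested.

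The extracellular matrix genes moved together as well. If the number in a probe's name is a position, it is argued against as the whole cause by a percentile of 99.68 among random lists with the same numbers. The letter in the name was not matched, so position by letter stays open. The level of the arrays, taken as their median, is argued against by 98.77 with arrays centred on it. This does not settle the level near the floor, since 3 of the 6 members were clear of it in no mouse. Quantile normalization, which also evens out the distribution of signals, gave 95.24, under the limit, so differences in that distribution stay open. With 50% of the floor subtracted the list lay at 98.95. Part of the floor then stayed in the values, so this does not decide on the floor as added background. The floor as a factor stays open too, since dividing each array by it gave 77.13. A difference between the number runs cannot be told apart from the pattern, with a percentile of 90 under a term for the run and too few samples to go further. Sample 202 alone may also account for it, as the percentile without it was 83.83 and all 6 members were at or tied for their lowest value there; no biological explanation was tested.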

How the results depend on the processing

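The number of probes clear of the floor in all mice (57) ranged from 39 to 84 over its alternatives, and the number of pairs of list scores was 0 in every setting run, which says little of stability, since fewer mice or pairings within number runs leave few permutations. The median SD (0.27) fell to 0.20 with arrays centred on their median, 0.17 with quantile normalization, 0.15 with a pseudocount, 0.19 with the median absolute deviation, 0.20 with arrays divided by their floor and 0.18 without samples 202 and 203, and rose to 0.34 with 50% of the floor subtracted; leaving out 1 mouse gave 0.20 to 0.28, lowest without sample 202. The median correlation between arrays ranged from 0.960 to 0.980 when 1 mouse was left out, lowest without sample 175. The 12 probes with an SD above 0.5 became 37 with 50% of the floor subtracted, 4 with a term for the number run and 6 with only probes clear of the floor. The 0 lists apart in spread became 3 with unmatched random lists, 3 with the run term (fast contractile, adhesion and growth factor genes), 1 each with quantile normalization, a pseudocount, arrays divided by their floor and without samples 202 and 203, and 0 to 2 when 1 mouse was left out. The 2 lists apart in covariation became 1 with unmatched random lists, 1 with arrays divided by their floor, and 0 each with the run term, without samples 202 and 203, and with only probes clear of the floor, where neither list kept 3 members. It rose to 3 with arrays centred on their median (glucose metabolism at 98.87), without the dimmest 25% of probes, with Spearman's correlation and without sample 175 or 177. With quantile normalization the count stayed at 2, but the extracellular matrix list fell to percentile 95.24 and the growth factor list rose to 98.06. The 14 probes between number runs became 2 with only probes clear of the floor, 22 with arrays divided by their floor, and 0 to 20 when 1 mouse was left out: 0 without sample 202, 2 without 203, 5 without 176 and 8 without 175. Fits with 1 sample left in a run assume that it varies like the others. The fewer samples or probes are part of these settings; otherwise the cause was not tested. Subtracting 80% of the floor was tried first for the 2 matrix lists and could not be used, since 21 probes then reach 0. Of 575 recomputed SDs of the 40 named probes, 453 stayed within 1 standard error, 88 were lower and 34 higher. Signals near the floor and the step of 0.1 per mille limit what dim probes can show. No paired analysis was possible because the labels give a single group.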

Other observations

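The count of probes for each split of the samples was planned, though how to read it was set afterwards. All other tests in this part were chosen after the differences between the samples had been seen. Outside the fixed lists, 18 probes were clear of the floor in all 6 mice, 16 of them with a gene name. They included the adhesive matrix protein Tnxb at 1.62 ± 0.240 per mille, the kinase Dmpk, whose gene is expanded in myotonic dystrophy, at 2.70 ± 0.865, the transcriptional regulator Cited2 at 1.97 ± 0.641, and the progenitor and endothelial surface protein Cd34 at 1.95 ± 0.451 per mille (SD, n = 6). Also clear were the growth factor receptors Igf2r at 1.65 ± 0.207 and Fgfr2 at 3.05 ± 0.606, the ligand Vegfb at 1.97 ± 0.393 and the lipoprotein receptor Vldlr at 1.87 ± 0.197 per mille (SD, n = 6). Vegfb was thus clear in every mouse on an array on which Vegfa was clear in none, though spots of different probes are not comparable in level.

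Some probes of genes best known from other tissues were clear of the floor. Eno2, the neuronal enolase, gave 3.67 ± 0.288 per mille, Slc2a2, the liver and islet glucose transporter, 1.57 ± 0.266, and the brain aldolase Aldoc 3.95 ± 0.723 per mille (SD, n = 6). Relatives of these genes, such as Slc2a4 and Aldoa, were clear of the floor as well. Cross-hybridization could not be examined, so these signals need not come from the named genes. Pole2, a subunit of a replicative DNA polymerase, gave 3.42 ± 0.271 per mille (SD, n = 6), whereas Pcna, its clamp, was clear in no mouse. The 28S ribosomal RNA probe ranged from 79.0 per mille in sample 177 to 182 per mille in sample 175.

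The 10 probes higher in samples 202 and 203 are the pattern most worth a second look. Of the 15 ways to split the samples into 4 and 2, 1 called as many as 14 probes, namely the real split, and the highest of the others called 0, but 15 splits are too few for a share under 0.05. Array-wide scaling is argued against as the whole account, since the median shift of the 10 probes was still 1.11 on the log2 scale after quantile normalization. The 10 were picked for their shift in these same data, and 7 of them passed a limma adjusted p of 0.05 after that step. Rounding is argued against too, as it could move none of them by over 0.14 against a smallest observed shift of 0.66. A local effect on the arrays stays open for part of it: if probe names are positions, the 28 neighbours of these probes had a median log2 shift of -0.02 against -0.20 for all other probes, at percentile 99.86 of random sets, though far below the 0.66 to 2.55 of the probes themselves. Handling of the samples in 2 batches and a difference between 2 cohorts of mice cannot be told apart, since the labels do not say what the numbers stand for; sample 175 lay at a median position of 0.255 between samples 176 to 178 (0) and 202 and 203 (1), from -0.18 for Ang to 0.66 for Il6st, so a step shared by 202 and 203 alone may not be the whole account.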
